A study of Homo sapiens with 6 samples.

How the data were processed

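RNA-seq values of 6 libraries were analysed, 3 from MCF10A cells with the empty pMSCVpuro vector and 3 from cells with the pre-miR-203a insert. Groups and replicate numbers were taken from the sample titles. The series text and the molecule field describe total RNA, while the extract protocol in the labels describes an immunoprecipitation of AGO2 before mRNA purification and TruSeq library preparation. Which of these applied to the libraries could not be settled from the labels. A RIP-seq data set that the series text mentions was not analysed here.

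Per the submitters' processing notes the build was hg38 and the tools were FastQC 0.11.5, MultiQC 1.6, featureCounts 2.0.0 and DESeq2 1.28.1. The aligner, the annotation release and the strand setting were not given in the sources used here. The authors deposited a table of FPKM values, scaled to the length of each feature and to the reads over all listed features, for 18999 features in each library. A second deposited table held TPM values, gene coordinates and the authors' DESeq2 comparison, with a baseMean signal, the mean over libraries of reads divided by size factors, log2 fold changes of control over pre-miR-203a, and p-values and adjusted p-values. The sign of the authors' log2 fold changes was turned here to pre-miR-203a over control. The smallest listed baseMean was 0.955, so features below about that level were not analysed here. The adjusted p of the deposited table was empty for 4790 features.

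No column of raw counts was among the files, so the test for counts fixed beforehand gave way to the one fixed for normalised values. Limma 3.58.1 in R 4.3.3 fitted log2(FPKM + 1) with the group as the only term, using eBayes with a mean trend and robust variances. Features entered with FPKM of 1 or more in at least 3 libraries, 11271 in all, of which 123 were repeat families. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low features. Reads per feature were recovered from FPKM and the deposited baseMean, and 100% of values came out whole within 0.01. Their totals give the depths, from 7632063 to 35084590 reads, and each total covers the listed features only. Replicates were not copies of 1 library, since their recovered reads differed by a chi-square of 11.1 to 88.3 per feature.

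Deviations from the group means went together most between libraries with the same replicate number, with correlations of 0.433, 0.269 and 0.321, all above 0.1. Between libraries with different numbers the correlations ranged from −0.417 to 0.221. The highest of these, for empty-vector library 1 and pre-miR-203a library 2, was also above 0.1. The labels do not state a shared batch or day. The fit with the replicate number as a block was fixed beforehand as a second fit, and its value stands beside a result where it changes the call.

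In all 29 gene lists with 641 entries were fixed before the data were examined, and 579 entries matched a listed feature by Ensembl identifier, of which 492 were tested. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, with adjustment over the 28 lists that had at least 2 tested members. Camera with an estimated correlation and fry were alternatives. With an estimated correlation camera has only the few residual degrees of freedom of the libraries, so its p rises for that reason too. Some lists share members, among them AXL, LOX, TNC, COL4A1, COL1A1, LASP1 and SNAI2. The named genes followed a rule fixed before the data were examined. They are the features of the miR-203 locus; the 12 largest changes in each direction among called genes with mean FPKM of 1 or more whose groups did not overlap, leaving out clone-based names; up to 4 called members per list with the smallest p, or the 2 with the smallest p where none was called; the 10 largest falls among genes with an 8mer; and 8 reported targets. It gave 115 genes. CORO1A, CD68, ITGAM, FCER1G and CD79A were named after their values were seen.

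For the target comparison, 3′ UTRs were taken from GENCODE 29 on GRCh38 and joined by Ensembl identifier without the version. The longest annotated 3′ UTR of each gene was searched on the sense strand, and 10185 tested features had one. Every one of 62651 coding transcripts had a stop codon just before the extracted 3′ UTR. The difference of medians was tested by permutation over genes with 1e+05 resamples, and with 1000 in the other settings. Linear models with the log of 3′ UTR length and with GC content gave the length-adjusted effect. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

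The tests were tried on simulated data. With 200 changed genes among 11214 simulated for this comparison, limma-trend recovered 29.9% of 1.5-fold, 86.6% of 2-fold and 100% of 4-fold changes, with 10 false calls. Changes of 1.5-fold were thus mostly missed with 3 libraries per group. All simulated genes had the same dispersion, 0.0199, so these shares do not hold for genes that vary more. A planted list was found with an adjusted p of 4.8e-49 in limma's camera, and 0 other lists were called in that simulation. The simulated genes varied independently, so it cannot show how often lists of genes that move together are falsely called. In the data the estimated correlation was 0.68 for the S phase list and 0.74 for the mitosis list. A planted shift of −0.2 in genes with a match was recovered as −0.201 in the comparison of medians and as −0.215 in the 7-mer scan. Level-matched sets of long noncoding RNAs gave p = 0.0001 with a planted rise and 0.602 without (permutation).

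Other settings fixed beforehand were other filters, a pseudocount of 0.1, the replicate block, leaving out each library, stricter thresholds, other site classes and other list tests. Chosen after seeing the data were rescaling by the authors' size factors, rescaling to equal upper quartiles, a total without mitochondrial reads, limma-voom on recovered reads, leaving out both libraries numbered 3, thinning of reads, and the tests of microRNA host transcripts.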

Results

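The study set cells that carried extra copies of a microRNA hairpin against cells that did not. MCF10A, an immortalised but non-tumorigenic human mammary epithelial line, received a retroviral vector with the pre-miR-203a hairpin or the same vector without an insert, and transduced cells were selected with puromycin. The stated purpose was to find target genes of miR-203a, a microRNA known from stratified epithelia, where it marks cells that leave the proliferating layer. RNA was sequenced from 3 libraries per group. The deposited values covered 18999 features, of which 262 were repeat families.

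Reads over the listed features numbered 15724554, 35084590 and 28721937 in empty-vector libraries 1, 2 and 3. They numbered 16658840, 20831785 and 7632063 in pre-miR-203a libraries 1, 2 and 3, so that depth differed by up to 4.60 times. Reads of the mitochondrially encoded genes made up 5.66% ± 2.50 (SD, n = 3) in the empty-vector group and 6.12% ± 1.01 (SD, n = 3) in the pre-miR-203a group. The first principal component of log2(FPKM + 1) held 53.2% of the variance and separated the groups. The second held 26.6% and set both libraries numbered 3 apart from the other libraries. Nothing in the labels states that the libraries came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

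MIR203A, the hairpin that the vector carried, had FPKM of 4.63, 5.44 and 6.96 in the empty-vector libraries and 19005, 3699 and 24945 in the pre-miR-203a libraries. The underlying reads numbered 8, 21 and 22 against 34827, 8476 and 20942. Its log2 fold change was 10.83 ± 0.66 (SE; adjusted p = 0.0014, limma). The annotated hairpin of 110 nt (ENSG00000207568.1) lies on chromosome 14 at 104117405 to 104117514 on the + strand of GRCh38. The mature miR-203a-3p, GUGAAAUGUUUAGGACCACUAG, lies at 104117469 to 104117490, and miR-203a-5p at 104117431 to 104117455. MIR203B is annotated on the opposite strand at 104117418 to 104117503, and reads of the 2 hairpins could not be told apart because the strand setting of the counting was not given in the sources used here. Reads from the vector and from the chromosomal locus could not be told apart either. In the authors' deposited table the log2 fold change of MIR203A was 11.46 with an SE of 0.80.

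Cells with pre-miR-203a held less RNA of nearly all measured DNA replication and mitosis genes and of C12orf75, PARK7, PRDX3 and LASP1. They held more RNA of 6 of 11 luminal epithelial genes, of 9 of 21 cell junction genes, of TRIM31, S100P and PSCA, and of several microRNA precursors. With an estimated correlation between genes no list was past the threshold, and the adjusted p was 0.436 for replication, 0.496 for mitosis, 0.216 for luminal and 0.235 for junction genes (limma's camera). That form of the test has few residual degrees of freedom, so its higher p does not reflect correlation between genes alone. Without empty-vector library 3 the luminal list had an estimated correlation of −0.068, below the preset 0.01. Its unadjusted p was still 0.0138, against 7.1e-07 with the preset (limma's camera). Genes with a match to the seed of miR-203a-3p in the 3′ UTR were lower as a set than genes without one. The test was limma-trend on log2(FPKM + 1), over 11271 features with FPKM of 1 or more in at least 3 libraries. It placed 1778 features past the threshold of 0.05 on the adjusted p, with 743 higher and 1035 lower in the pre-miR-203a group, and 3392 had an unadjusted p under 0.05. Among protein-coding genes 695 of 10204 tested were higher and 1010 lower, and among long noncoding RNAs 31 of 537 were higher and 14 lower. Annotated microRNA hairpins gave 8 higher and 0 lower of 40 tested, repeat families 3 higher and 1 lower of 123, and all other features 6 higher and 10 lower of 367. Of the hairpins 8 were higher and 1 lower at an unadjusted p under 0.05, and limma-voom on recovered reads called 7 higher and 0 lower. The groups did not overlap for any of the 1778, against 37.5% of all tested features and 10% by chance. Without empty-vector library 1, 2 or pre-miR-203a library 1 the count fell to 745, 900 and 883, and the higher genes also fell from 743 to 441 without empty-vector library 3. The authors' deposited table gave 2594 features an adjusted p under 0.05 from DESeq2, not limma, of which 2321 were tested here, and the 1743 called in both had the same direction.

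**Figure D1:**
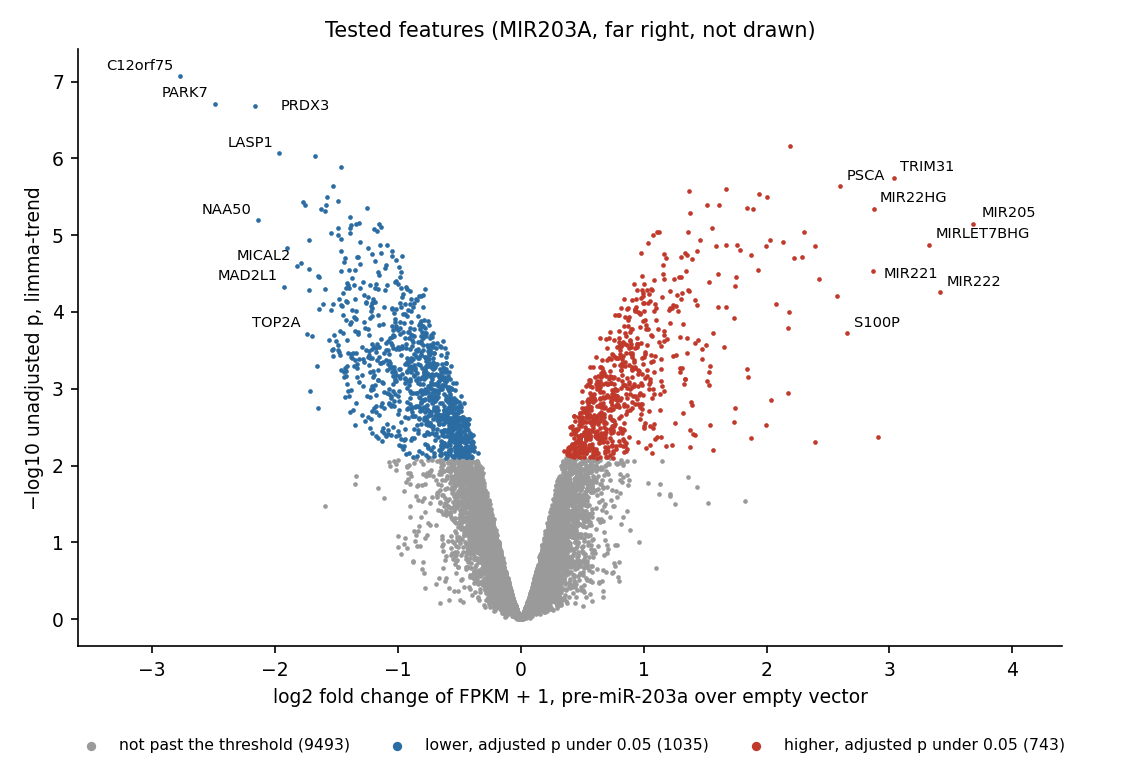
Each point is a tested feature. The x axis is the log2 fold change of FPKM + 1, pre-miR-203a over empty vector, and the y axis is −log10 of the unadjusted limma-trend p. The 743 higher features are red and the 1035 lower are blue, with C12orf75 and PARK7 at the far left.

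The largest fall on the scale of log2(FPKM + 1) was that of C12orf75 (ENSG00000235162.9; chromosome 12, 105235290 to 105396097), from an FPKM of 19.2 ± 3.05 to 1.93 ± 0.09 (SD, n = 3 each). Its log2 fold change was −2.78 ± 0.13 (SE; adjusted p = 7.7e-04, limma), and its 3′ UTR of 918 nt holds a 7mer-m8 match to miR-203a-3p. PARK7 (ENSG00000116288.13; chromosome 1, 7954291 to 7985505), which encodes the redox-sensitive protein DJ-1, fell from 107 ± 3.90 to 18.5 ± 2.98 (log2 fold change −2.49 ± 0.13). PRDX3, a mitochondrial peroxidase, fell from 71.4 ± 2.45 to 15.2 ± 1.96 (−2.16 ± 0.12). Neither PARK7 nor PRDX3 has a 6mer match in the 3′ UTR. NAA50, an N-terminal acetyltransferase, and LASP1, an actin-binding protein, had log2 fold changes of −2.14 ± 0.19 and −1.96 ± 0.13, and both hold a 7mer-m8 match. The other genes among the 12 largest falls were MAD2L1 (−1.93 ± 0.23) and SPC24 (−1.90 ± 0.19), both of the kinetochore, MICAL2 (−1.82 ± 0.20), MCM10 (−1.79 ± 0.19), DTL (−1.78 ± 0.15), BOLA3 (−1.75 ± 0.15) and TOP2A (−1.74 ± 0.25). MCM10, DTL and TOP2A act in DNA replication and chromosome structure. The 12 genes had adjusted p of at most 0.0065 (limma), and each fell in every pre-miR-203a library.

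The 10 largest falls among genes with an 8mer match were those of MAD2L1, SPC24, TXNRD1, COPS4, BIRC5, TYMS, KITLG, BANF1, PHLDA1 and PRPS2. TXNRD1, the cytosolic thioredoxin reductase, fell from 59.5 ± 5.83 to 17.5 ± 3.62 (log2 fold change −1.73 ± 0.17). COPS4, a subunit of the COP9 signalosome, fell from 16.2 ± 1.11 to 4.41 ± 0.41 (−1.67 ± 0.11). BIRC5, which encodes survivin, and TYMS, the thymidylate synthase, had log2 fold changes of −1.65 ± 0.28 and −1.61 ± 0.21. KITLG, the KIT ligand, BANF1, PHLDA1 and PRPS2 had log2 fold changes of −1.55 ± 0.20, −1.53 ± 0.24, −1.53 ± 0.25 and −1.49 ± 0.14. Adjusted p was at most 0.0098 for all 10 (limma).

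On the fitted scale of log2(FPKM + 1), which draws in changes at low FPKM, MIR205 had the highest log2 fold change after MIR203A, from 2.84 ± 0.53 to 51.7 ± 21.9 FPKM (SD, n = 3 each; log2 fold change 3.68 ± 0.33; adjusted p = 0.0022, limma). MIR205 lies within the long noncoding RNA MIR205HG, and reads of the 2 could be split by the counting. MIR222 had 0 reads in the empty-vector libraries and 20, 10 and 15 in the pre-miR-203a libraries, which made it at least 26.4-fold higher against a floor of 3 counts over the group, for counting error only. MIRLET7BHG, MIR22HG and MIR200CHG, the host transcripts of let-7b, miR-22 and miR-200c, had log2 fold changes of 3.32 ± 0.33, 2.87 ± 0.24 and 2.42 ± 0.28. MIR221 and MIR27B had log2 fold changes of 2.86 ± 0.32 and 2.40 ± 0.60 on few reads, and MIR27B had 1, 1 and 0 reads against 19, 19 and 1. Among protein-coding genes TRIM31, a ubiquitin ligase, rose from 1.19 ± 0.44 to 17.1 ± 4.41 FPKM (3.04 ± 0.22). S100P, a calcium-binding protein, rose from 163 ± 79.5 to 935 ± 98.9 (2.66 ± 0.39), PSCA, a GPI-anchored surface protein, from 23.0 ± 4.78 to 144 ± 28.6 (2.60 ± 0.20), and PRR15L from 1.72 ± 0.89 to 15.2 ± 5.81 (2.58 ± 0.32). Adjusted p was at most 0.0065 for these features except MIR27B, at 0.036 (limma). The call of MIR27B ended without any single library other than pre-miR-203a library 3, with an adjusted p of 0.088 to 0.113 (limma).

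Of the 25 members of the S phase list 24 fell, and 25 were lower adjusted over the list alone. Examples were CDC45 (24.1 ± 3.69 to 8.28 ± 1.05 FPKM; log2 fold change −1.43 ± 0.15), POLE2 (−1.10 ± 0.12), RRM2 (−1.59 ± 0.19) and RFC2 (−0.91 ± 0.11). The list was lower than other genes with an adjusted p of 4.3e-17 in limma's camera with a preset correlation of 0.01. With an estimated correlation the adjusted p was 0.436 in camera of limma. Of the 24 tested members of the mitosis list 23 fell, and 24 were lower adjusted over the list alone. CDK1, the mitotic cyclin-dependent kinase, fell from 64.6 ± 13.5 to 19.8 ± 3.56 FPKM (−1.65 ± 0.19), and BUB1, a spindle checkpoint kinase, had a log2 fold change of −1.35 ± 0.18, beside MAD2L1 and TOP2A. The adjusted p of the list was 3.0e-14 (limma's camera) and 0.496 with an estimated correlation. Of 7 tested replication-dependent histone genes 5 rose, and 7 were higher adjusted over the list alone, with 2 called by limma-voom on recovered reads and with H2BC5 (1.00 ± 0.13), H2AC6 (1.08 ± 0.18), H2AC13 (0.66 ± 0.14) and H2BC4 (0.63 ± 0.14) as examples. The adjusted p was 5.1e-05 (limma's camera) and 0.235 with an estimated correlation. Histone genes are near-identical copies, and how the counting shared their reads is uncertain. Only 7 of the 24 listed histone genes were tested, and the examples had low mean FPKM, 0.44 to 4.18 in the empty-vector group. How well the mRNA purification of the extract protocol captured histone transcripts was not tested. The calls of H2AC13 and H2BC4 ended without empty-vector library 1 or 2 or pre-miR-203a library 1, and that of H2AC13 also without pre-miR-203a library 2, with adjusted p of up to 0.102 and 0.105 (limma).

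**Figure D2:**
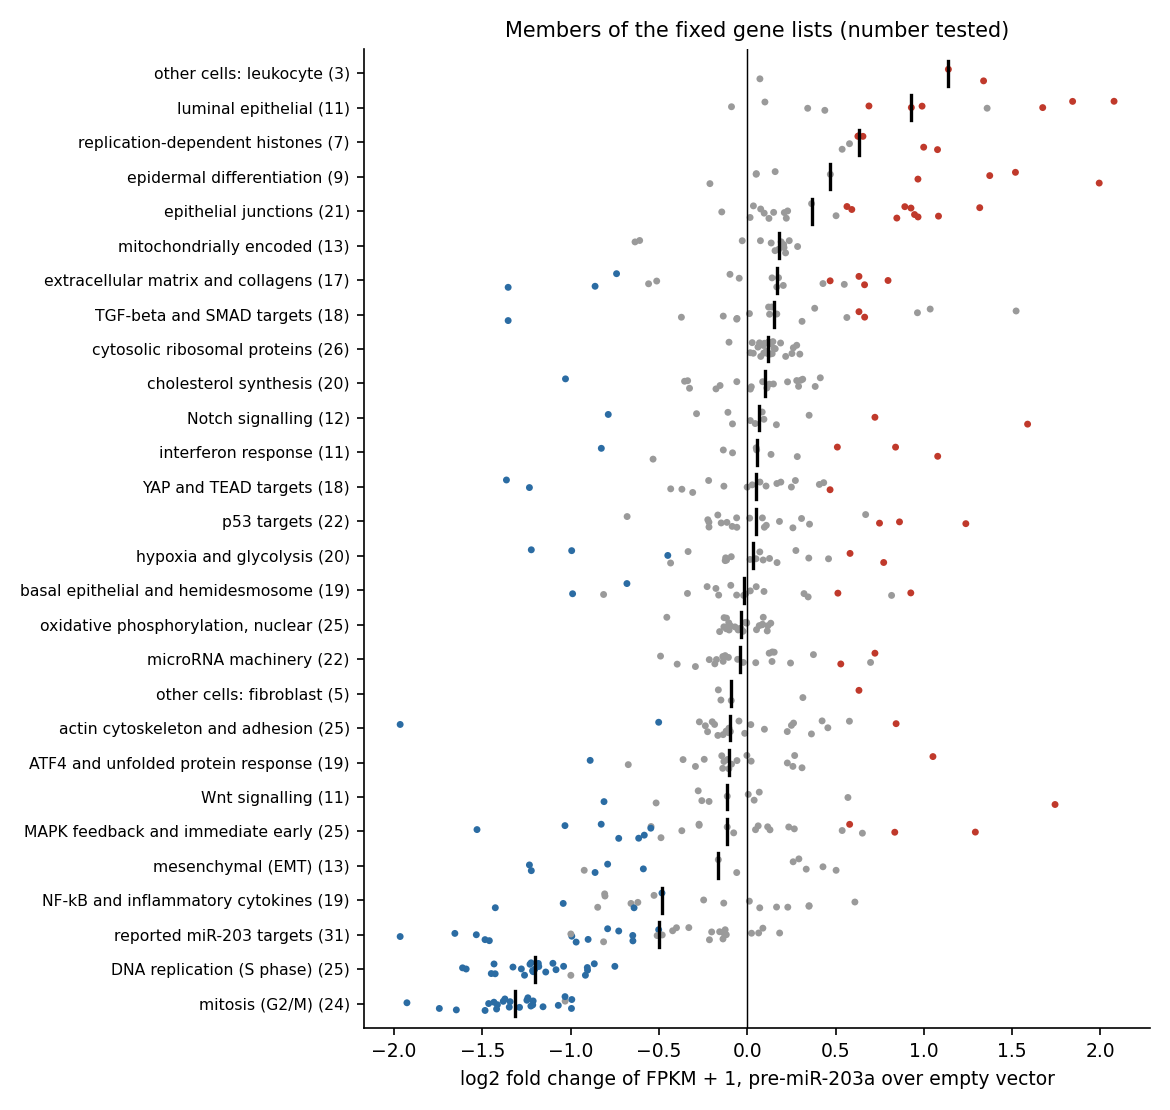
Each point is a tested member of a list fixed before the data were examined, and the x axis is its log2 fold change of FPKM + 1. Red and blue points are past the threshold, black bars are medians, and the number tested stands in parentheses. The S phase and mitosis lists have medians of −1.20 and −1.32, and the endothelial list, with 1 tested member, is not drawn.

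Of the 11 tested luminal epithelial genes 6 rose and 0 fell, with 8 higher and 0 lower at an unadjusted limma p under 0.05, and 8 were higher adjusted over the list alone. CLDN4, a tight junction protein, rose from 8.73 ± 1.91 to 29.6 ± 2.10 FPKM (log2 fold change 1.67 ± 0.16) and ELF3, an epithelial transcription factor, from 3.05 ± 1.40 to 15.4 ± 1.48 (2.08 ± 0.26). GATA3 and KRT8 had log2 fold changes of 0.99 ± 0.16 and 0.93 ± 0.16. The adjusted p was 1.4e-05 (limma's camera) and 0.216 with an estimated correlation. Of the 21 epithelial junction genes 9 rose and 0 fell, with 11 higher and 0 lower at an unadjusted limma p under 0.05 and 11 higher adjusted over the list alone, and the examples were CLDN1 (1.32 ± 0.18), JUP (0.89 ± 0.14), OCLN (0.93 ± 0.14) and CDH1, which encodes E-cadherin (0.85 ± 0.14). Its adjusted p was 6.3e-06 (limma's camera) and 0.235 with an estimated correlation. Of the 9 tested epidermal differentiation genes 4 rose, the keratin KRT13 (1.52 ± 0.28), the transglutaminase TGM1 (0.97 ± 0.20) and the cornified envelope genes SPRR1A (1.99 ± 0.46) and SPRR1B (1.37 ± 0.32), and the same number was higher adjusted over the list alone. SPRR1A and SPRR1B are close paralogs whose reads may be shared. The adjusted p was 0.0277 (limma's camera), 0.680 with an estimated correlation, and 0.154 without pre-miR-203a library 3. The calls of SPRR1A and SPRR1B ended without empty-vector library 2 or 3 or pre-miR-203a library 1 or 3, and that of TGM1 without empty-vector library 2 or 3 or pre-miR-203a library 1 or 2, with adjusted p of up to 0.105 (limma).

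Among 19 basal epithelial genes 2 rose and 2 fell, with an adjusted p of 0.872 for the list (limma's camera), and 2 were higher and 3 lower adjusted over the list alone. TRIM29 rose (log2 fold change 0.93 ± 0.12) and ITGB4, a hemidesmosome integrin, was higher (0.51 ± 0.14; adjusted p = 0.049, limma, and 0.053 with the replicate number as a block). COL17A1 (−0.99 ± 0.20) and the basal keratin KRT5 (617 ± 74.2 to 383 ± 26.5 FPKM; −0.68 ± 0.14) fell. The call of ITGB4 ended without any 1 library, that of KRT5 without library 1 or 2 of either group, and that of COL17A1 without empty-vector library 3 or pre-miR-203a library 1 or 2, with adjusted p of up to 0.188, 0.096 and 0.060 (limma). Among 13 mesenchymal genes 5 fell and 0 rose, with 6 lower and 0 higher at an unadjusted limma p under 0.05, 6 lower adjusted over the list alone and an adjusted p of 0.324 for the list (limma's camera). The receptor kinase AXL fell from 44.8 ± 9.04 to 18.6 ± 4.21 FPKM (−1.23 ± 0.20), and TNC (−0.86 ± 0.15), the collagen-crosslinking enzyme LOX (−1.22 ± 0.27) and the transcription factor SNAI2 (−0.79 ± 0.18) were also lower. The call of LOX ended without empty-vector library 1 or 2, and that of SNAI2 without empty-vector library 1 or 3 or pre-miR-203a library 2, with adjusted p of up to 0.081 and 0.076 (limma).

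Of 31 tested genes reported elsewhere as miR-203 targets 13 fell and 0 rose, with 19 lower and 0 higher at an unadjusted limma p under 0.05 and 19 lower adjusted over the list alone. SRC, a tyrosine kinase, fell from 22.6 ± 2.54 to 7.42 ± 0.51 FPKM (log2 fold change −1.48 ± 0.12). RUNX2 (−0.90 ± 0.11) and CDK6 (−1.46 ± 0.19), like SRC, hold an 8mer match, and LASP1 had the largest fall of the list. The adjusted p of the list was 3.1e-07 (limma's camera) and 0.216 with an estimated correlation. Of the targets named beforehand, BMI1, a Polycomb protein, was lower (−0.65 ± 0.17; adjusted p = 0.039, limma), and CAV1 was lower at −0.50 ± 0.13 (adjusted p = 0.044, limma, and 0.058 with the replicate number as a block). TP63, the transcription factor of basal epithelia, had a log2 fold change of −0.81 ± 0.23 (adjusted p = 0.053, limma, and 0.026 with the block). Without pre-miR-203a library 2 TP63 had an adjusted p of 0.0236 (limma), and in the authors' deposited table it had a log2 fold change of −0.88 with an adjusted p of 0.0091 from DESeq2, not limma. ABL1, which also holds an 8mer match, did not differ beyond the spread between libraries (−0.16 ± 0.14; adjusted p = 0.52, limma). SOCS3 and ZEB2 lay under the filter and were not tested. SOCS3 had FPKM of 0.84, 0.85 and 0.89 against 0.55, 0.56 and 0.72, and ZEB2 0.52, 0.30 and 0.29 against 0.93, 0.97 and 0.57. The call of BMI1 ended without any empty-vector library or pre-miR-203a library 1, and that of CAV1 without any 1 library, with adjusted p of up to 0.121 and 0.163 (limma).

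Of 19 NF-kB and cytokine genes 4 fell and 0 rose (8 and 1 at an unadjusted limma p under 0.05), the same adjusted over the list alone, and these were the chemokines CXCL1 (22.1 ± 7.92 to 7.38 ± 1.56 FPKM; log2 fold change −1.43 ± 0.25), CXCL2 (−1.04 ± 0.19) and CXCL3 (−0.64 ± 0.16), which are close paralogs, and NFKB1 (−0.48 ± 0.11). The list had an adjusted p of 0.135 (limma's camera), and 0.0497 with the replicate number as a block, 0.0324 without empty-vector library 1 and 0.0389 without empty-vector library 2. It was past the threshold in these 3 of 16 other settings only, with 0.471 without empty-vector library 3, 0.494 without pre-miR-203a library 2, 0.273 with limma's fry, 0.936 with an estimated correlation and 0.890 with that and the block. Of 25 MAPK feedback genes 3 rose and 7 fell (adjusted p = 0.554, limma's camera), and 4 rose and 7 fell adjusted over the list alone. The phosphatase DUSP1 rose from 72.6 ± 16.5 to 179 ± 37.5 FPKM (1.29 ± 0.22), and PHLDA1, the EGFR ligand AREG (−1.03 ± 0.18) and SPRY4 (−0.61 ± 0.11) fell. Of 12 Notch genes 2 rose and 1 fell (adjusted p = 0.465, limma's camera), the same adjusted over the list alone. The receptor NOTCH3 rose from 1.52 ± 0.38 to 6.54 ± 0.91 FPKM (1.59 ± 0.16), LFNG was higher (0.72 ± 0.17) and the ligand JAG1 fell (−0.79 ± 0.11). Of 11 Wnt genes 1 rose, the inhibitor DKK1 (32.2 ± 4.78 to 112 ± 26.7 FPKM; 1.74 ± 0.21), and 1 fell, TCF7 (−0.81 ± 0.12), with 2 and 2 adjusted over the list alone and an adjusted p of 0.864 (limma's camera). The Wnt median was −0.11 with the test in the same direction, and the mean was 0.02. The call of SPRY4 ended without empty-vector library 1, those of CXCL3 and LFNG without empty-vector library 1 or 3 or any pre-miR-203a library, and that of NFKB1 without any library but pre-miR-203a library 3, with adjusted p of up to 0.125 (limma).

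Of 22 p53 target genes 3 rose, TP53I3 (log2 fold change 1.24 ± 0.20), BTG2 (0.86 ± 0.16) and TP53INP1 (0.75 ± 0.17), and 0 fell, with 4 higher and 1 lower at an unadjusted limma p under 0.05, 3 higher and 1 lower adjusted over the list alone and an adjusted p of 0.381 (limma's camera). Of 11 interferon response genes IFIT2 (1.08 ± 0.25), OAS1 (0.51 ± 0.13) and STAT2 (0.84 ± 0.22) were higher and OAS3 (−0.83 ± 0.16) was lower, the same numbers adjusted over the list alone, and the adjusted p was 0.554 (limma's camera). Of 18 YAP and TEAD targets 1 rose and 2 fell (adjusted p = 0.864, limma's camera), with 2 and 2 adjusted over the list alone, a median of 0.05, a mean of −0.09 and an upward test. AXL and NT5E (−1.36 ± 0.29) fell and LATS2 was higher (0.47 ± 0.12; adjusted p = 0.037, limma, and 0.069 with the replicate number as a block). Of 18 TGF-beta targets COL1A1 (0.63 ± 0.12) and BAMBI (0.67 ± 0.13) rose and COL4A1, a basement membrane collagen, fell from 7.77 ± 1.56 to 2.40 ± 0.15 FPKM (−1.35 ± 0.15), the same numbers adjusted over the list alone (adjusted p = 0.195, limma's camera). Calls ended without empty-vector library 2 or pre-miR-203a library 1 for BTG2, without either of empty-vector libraries 1 and 2 or pre-miR-203a library 1 for BAMBI, without empty-vector library 1 or pre-miR-203a library 1 for COL1A1, and without pre-miR-203a library 1 or 2 for NT5E. They ended without empty-vector library 2 or 3 for OAS3 and without any library but pre-miR-203a library 3 for TP53INP1, IFIT2, OAS1, STAT2 and LATS2, with adjusted p of up to 0.167 (limma).

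Of 17 matrix genes 4 rose and 3 fell, the same adjusted over the list alone, with an adjusted p of 0.613 (limma's camera). LAMA4 rose (log2 fold change 0.80 ± 0.11), while COL4A1, TNC and FBN2 (−0.74 ± 0.13) fell. Of 25 actin and adhesion genes 1 rose, RHOB (0.84 ± 0.19), and LASP1 and CAV1 were lower, with 1 and 1 adjusted over the list alone and an adjusted p of 0.864 (limma's camera). Of 20 hypoxia and glycolysis genes BNIP3L (0.58 ± 0.11) and ADM (0.77 ± 0.16) rose and 3 fell, among them PFKFB3 (−0.99 ± 0.17) and LOX, the same numbers adjusted over the list alone. Its adjusted p was 0.872 (limma's camera), with a median of 0.03, a mean of −0.05 and a downward test. Of 19 ATF4 and unfolded protein response genes DNAJB9 rose (1.05 ± 0.19) and PSAT1, an enzyme of serine synthesis, fell (−0.89 ± 0.14), the same adjusted over the list alone (adjusted p = 0.864, limma's camera). Of 20 cholesterol synthesis genes INSIG1 fell (−1.03 ± 0.21), also adjusted over the list alone, and 0 rose, also at an unadjusted p under 0.05 (adjusted p = 0.830, limma's camera). The calls of FBN2 ended without empty-vector library 1, of INSIG1 without empty-vector library 1 or 3 or pre-miR-203a library 1, and of RHOB, BNIP3L and ADM without empty-vector library 1 or 2 or pre-miR-203a library 1, with adjusted p of up to 0.099 (limma).

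Of 22 genes of the microRNA machinery AGO4 (log2 fold change 0.53 ± 0.13) and DICER1 (8.68 ± 1.81 to 15.0 ± 3.03 FPKM; 0.72 ± 0.20) were higher over all genes and 0 adjusted over the list alone, with an adjusted p of 0.864 (limma's camera), a median of −0.04, a mean of 0.04 and an upward test. Both calls ended without any library but pre-miR-203a library 3, with adjusted p of up to 0.152 (limma). None of 25 nuclear oxidative phosphorylation genes, 13 mitochondrially encoded genes or 26 cytosolic ribosomal protein genes was past the threshold in limma-trend, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 1, 0 and 0 genes in these lists, and limma-voom on recovered reads called 1, 0 and 0. The smallest p in these lists were those of NDUFA9 (−0.45 ± 0.13) and UQCRFS1 (−0.16 ± 0.13), MT-ATP8 (−0.63 ± 0.37) and MT-ND6 (−0.61 ± 0.53), and RPL3 (0.28 ± 0.15) and RPL7A (0.30 ± 0.19). The lists had adjusted p of 0.864, 0.734 and 0.135 (limma's camera). The median of the mitochondrially encoded list was 0.18, above 0, unlike MT-ATP8 and MT-ND6. This list had an adjusted p of 0.0045, upward, without empty-vector library 3, and the ribosomal list 0.0091, also upward, without pre-miR-203a library 2 (limma's camera with the preset correlation). With a correlation estimated in the same libraries the adjusted p was 0.814 and 0.929 (limma's camera).

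Markers of other cell types were measured beside these groups. Of the leukocyte markers 3 were tested, and CSF1R (0.83 ± 0.26 to 3.04 ± 0.71 FPKM; log2 fold change 1.14 ± 0.18) and CD14 (9.69 ± 3.07 to 25.5 ± 4.53; 1.34 ± 0.24) rose, also adjusted over the list alone, while CORO1A had a log2 fold change of 0.07 ± 0.13. The list had an adjusted p of 0.0458 (limma's camera) and 0.680 with an estimated correlation, and 0.0743 and 0.0739 without pre-miR-203a library 1 and library 3. CD68, ITGAM, FCER1G and CD79A, abundant in myeloid or B cells, had mean FPKM of 0.07, 0.15, 0.19 and 0.10 in the empty-vector group and 0.08, 0.07, 0.30 and 0.07 in the pre-miR-203a group. Of 5 fibroblast markers COL1A1 rose, also adjusted over the list alone (adjusted p = 0.734, limma's camera), with a median of −0.09, a mean of 0.11 and an upward test. ENG, the 1 tested endothelial marker, had a log2 fold change of 0.14 ± 0.16, also not past the threshold adjusted over the list alone, and a set test was not run.

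The remaining comparison asked whether predicted targets of miR-203a-3p moved as a set. A 7mer-m8 match, CATTTCA, pairs with bases 2 to 8 of the microRNA, and an 8mer, CATTTCAA, adds an A opposite base 1. The longest annotated 3′ UTR held 1 of these matches or more in 2323 tested genes and not even a 6mer in 5097. The median log2 fold change of the genes with a match was 0.149 lower, a shift of −0.149 (permutation test over genes with 1e+05 resamples, two-sided p = 1e-05, the smallest possible). Genes are not independent replicates, so the shift was also set against all 210 7-mers made of the same bases, among which it ranked 1, with −0.131 as the next. That next 7-mer, ACATTTC, pairs with bases 3 to 9 of the same microRNA. Medians were −0.17 for 748 genes with an 8mer, −0.09 for 1575 with a 7mer-m8, −0.05 for 1016 with a 7mer-A1, −0.01 for 1749 with a 6mer and 0.03 for the genes without a match. Of 1008 lower genes with a 3′ UTR 36.8% had a 7mer-m8 or 8mer, against 21.3% of the other genes (odds ratio 2.16, Fisher's exact p = 3.0e-26). Of 693 higher genes 16.7% had a match, against 23.3% (odds ratio 0.66, Fisher's exact p = 5.4e-05). DICER1, with an 8mer, and CLDN1 and DKK1, with a 7mer-m8, were among these higher genes. Both Fisher tests took genes as independent and left out 3′ UTR length. The median length was 3339 nt with an 8mer, 2967 nt with a 7mer-m8 and 727 nt without a match. With 3′ UTR length and GC content in a linear model the effect of a match was −0.138 ± 0.014 (SE), which ranked 1 of the 210 and nearly tied with that of ACATTTC (−0.1376 against −0.1372). It ranked 2, behind ACATTTC, without empty-vector library 2 (−0.138 against −0.139), without pre-miR-203a library 3 (−0.115 against −0.123) and without both libraries numbered 3 (−0.117 against −0.125). The shift of the medians was −0.072 with no filter on low values, −0.050 without pre-miR-203a library 3 and −0.012 without both libraries numbered 3, while the effect in the linear model was −0.115 and −0.117 without these libraries.

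**Figure D3:**
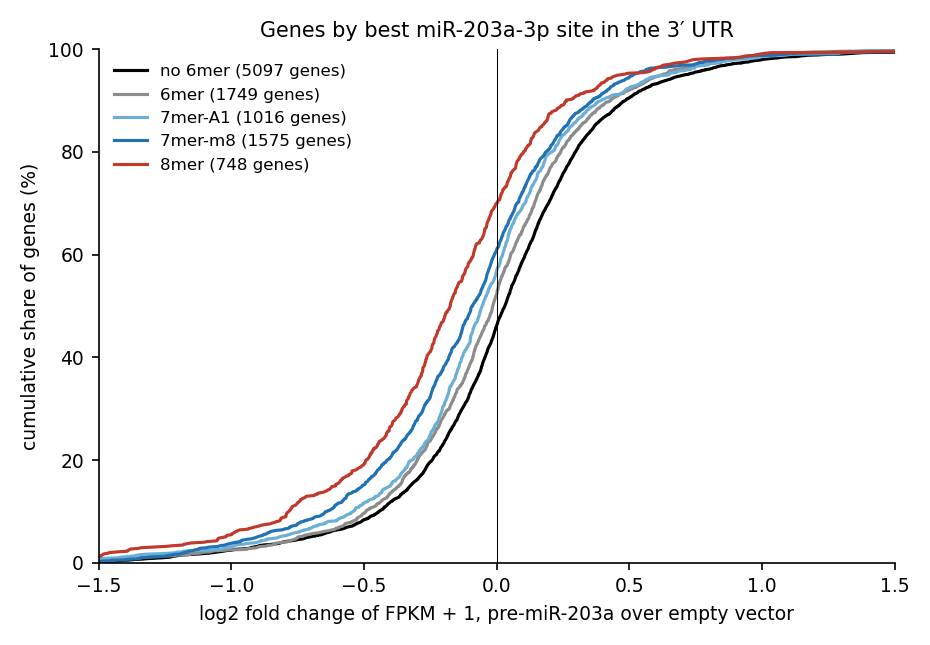
Cumulative share of genes (y axis, %) against the log2 fold change of FPKM + 1 (x axis), by the best miR-203a-3p match in the 3′ UTR. The curve of the 748 genes with an 8mer lies farthest to the left, at a median of −0.17, and that of the 5097 genes without a 6mer has a median of 0.03.

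Library by library, each empty-vector library was compared with the mean of the other empty-vector libraries, so that their linear-model values sum to 0, and each pre-miR-203a library with the mean of all 3. The effect of a match in the linear model was 0.0088, −0.0007 and −0.0080 in empty-vector libraries 1, 2 and 3. It was −0.120, −0.110 and −0.183 in pre-miR-203a libraries 1, 2 and 3, with standard errors of at most 0.016, and ranked 2, 2 and 1, with ACATTTC lower in libraries 1 and 2. Without length and GC content, the shift of the median was 0.013, −0.099 and 0.083 in the empty-vector libraries and −0.040, −0.035 and −0.357 in the pre-miR-203a libraries. Empty-vector library 2 then lay below pre-miR-203a libraries 1 and 2.

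**Figure D4:**
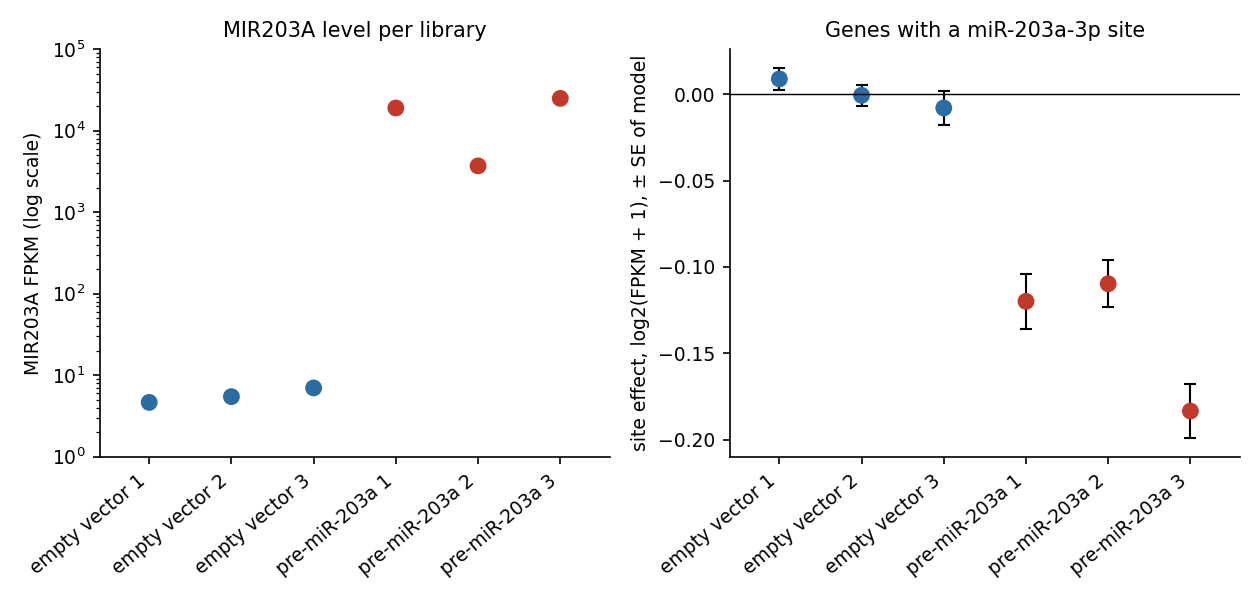
Left, MIR203A FPKM per library on a log axis, from 4.63 to 6.96 in the empty-vector libraries (blue) and from 3699 to 24945 in the pre-miR-203a libraries (red). Right, the effect of a 7mer-m8 or 8mer match per library on log2(FPKM + 1), with bars of ± SE of the linear model, between −0.183 and −0.110 in the pre-miR-203a libraries.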

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

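The count over splits, the model with 3′ UTR length and GC content in each library, and the test of AGO2-bound RNA were chosen after the result was seen. The test of cell-cycle genes without a match and the thinning of reads were written down before their results were seen. Of 7728 listed features outside the test, 0 combined at least 10 reads in every pre-miR-203a library with 0 reads in the empty-vector libraries. Groups of 3 libraries are too small for a test of single outlying libraries.

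The 6 libraries can be split into 3 against 3 in 10 ways. Only 1 of the 10 splits, the real one, gave as many as 1778 called features, and the highest of the others gave 0 (limma-trend). The other splits that part all 3 same-number pairs also gave 0. With 10 splits a share under 0.05 cannot be reached.

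Genes with a miR-203a-3p match in the 3′ UTR were lower in cells with the hairpin. Long or AU-rich 3′ UTRs hold more matches by chance, but with length and GC content in the model the effect was −0.1376 and stayed below 0 in all 16 other settings, from −0.163 to −0.115. It ranked 1 of 210 same-composition 7-mers, or 2 in 3 of these settings, and the nearest other 7-mer, ACATTTC at −0.1372, pairs with bases 3 to 9 of the same microRNA. If the libraries held AGO2-bound RNA, as the extract protocol reads, genes with a match would be enriched where the hairpin was present, and the highest effect among the pre-miR-203a libraries was −0.1097, in library 2. Without length and GC content the values were −0.040, −0.035 and −0.357, also below 0, but empty-vector library 2 had −0.099. A scan of 13612 7-mers ranked the match to bases 2 to 8 first. The pattern may therefore reflect repression by miR-203a-3p, as a hypothesis, and AGO2-bound RNA as the reason for other changes stays untested. The comparison of medians and its rank among same-composition 7-mers were fixed before the data were examined.

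Genes of DNA replication and mitosis were lower nearly throughout, 47 of 49 tested. Repression through 3′ UTR matches does not account for most of them, because the 31 genes without even a 6mer had a median log2 fold change of −1.23, and 30 of these were called, against −1.28 in the 6 genes with a 7mer-m8 or 8mer. The lower depth of the pre-miR-203a libraries does not account for them either, because 48 of 49 were lower with every library thinned to the reads of the shallowest. The fall may be an indirect effect of the hairpin, or the cultures may have differed in density or growth when harvested, and neither was tested.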

How the results depend on the processing

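The scalings, limma-voom, leaving out both libraries numbered 3 and the block with an estimated correlation were chosen after the result was seen. The planned settings for raw counts were not run because no counts column was among the files. The called features that each setting shared with the 1778 kept their direction. The number of calls was 1812 with equal upper quartiles, of which 51.7% were higher in place of 41.8%, 1830 with the authors' size factors, 1912 with limma-voom and 1970 with the replicate block. Leaving out 1 library gave 745 to 2257 calls, 323 to 919 higher and 422 to 1338 lower. Without both libraries numbered 3 there were 3190 (1239 higher, 1951 lower), at an adjusted p under 0.01 there were 617 (240 and 377, limma), and with an absolute log2 fold change of 1 or more 488 (189 and 299). The shift of the medians of genes with a match was −0.012 without both libraries numbered 3 (permutation p = 0.234). With 3′ UTR length and GC content in the linear model the effect in this setting was −0.117 ± 0.014 (SE). Why the medians of these libraries differed less was not tested further. Of 8 lists past the threshold, 0 remained with an estimated correlation, also with the block, and without any 1 library or both numbered 3 none of all lists had an adjusted p under 0.209 (limma's camera). These fits have few residual degrees of freedom and adjust over 28 lists, so they can neither uphold nor undo a list. Without pre-miR-203a library 2 the reported targets had an estimated correlation of −0.013. Their unadjusted p was 0.0075, against 1.4e-08 with the preset correlation (limma's camera). Limma's fry, which does not compare a list with other genes, gave adjusted p of 0.0069 for reported targets and for luminal genes. It was 0.0096 for histone, 0.0102 for junction and for S phase, and 0.0286 for mitosis genes (fry). Epidermal genes had 0.170 and leukocyte markers 0.0552, not past the threshold (fry). Without both libraries numbered 3 the oxidative phosphorylation list was lower, with a mean of −0.20 and an adjusted p of 0.018, and the mitochondrially encoded list higher, with 0.51 and 5.4e-05 (limma's camera), but both had 0.736 with an estimated correlation. The block changed no other call of a list or named gene than those given beside their results. The log2 fold change of MIR203A, at the miR-203 locus, ranged from 10.31 to 11.69. Of 104 named genes past the threshold 70 kept their call in all settings, 34 lost it without some single library, and 0 changed sign. Changes of 1.5-fold were mostly missed in the simulation.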

Other observations

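All tests of microRNA host transcripts and of the coding sequence were chosen after the result was seen, and only the test of miR-203a-5p was written down before. Cells with pre-miR-203a held more RNA of other microRNA precursors. Of 24 tested long noncoding RNAs that hold an annotated microRNA hairpin, 11 were higher and 0 lower (limma-trend; 9 to 12 higher in the other settings, with 1 lower without both libraries numbered 3). Their median log2 fold change was 0.74, against 0.01 for 513 other long noncoding RNAs, of which 20 were higher and 14 lower. In the other settings the median of the hosts ranged from 0.49, without both libraries numbered 3, to 1.00, with a pseudocount of 0.1. Examples were MIR205HG, from 28.3 ± 0.65 to 159 ± 51.1 FPKM (log2 fold change 2.39 ± 0.24), MIR31HG (1.53 ± 0.27), MIR100HG (1.46 ± 0.14), which holds let-7a-2, miR-100 and miR-125b-1, MIR193BHG (1.21 ± 0.16) and MIR17HG, the transcript of the miR-17 cluster (1.08 ± 0.25). The adjusted p of these was at most 0.0256 (limma). MIR222HG and MIR34AHG were not past the threshold, at 1.43 ± 0.48 and 0.11 ± 0.33. The 628 protein-coding host genes had a median of 0.01, against −0.02 for the other coding genes.

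The split by microRNA number was chosen after it was seen which hosts rose and only describes them. The 14 hosts of microRNAs numbered under 1000 had a median of 1.32 and the 10 others 0.18. Over 10 loci of microRNAs numbered under 1000 with both measured, the log2 fold change of the hairpin was above that of its host in 8, and the mean difference was 0.73 (exact sign-flip p = 0.0078, two-sided). Of the 22 other hairpins with a measured host 8 were above it, with a mean difference of −0.17. That test was set aside because the hairpins had few reads in the empty-vector libraries (MIR205 4, 13 and 9, MIR221 3, 11 and 3), and hairpin and host can share reads.

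A rise of long noncoding RNAs in general does not account for the higher hosts, because those without a hairpin had a median of 0.009596. That median does not speak to a rise of only some long noncoding RNAs. The rise of the hosts may come from competition of the abundant hairpin for microRNA processing, which would leave other primary transcripts uncut. It may also come from transcription of the host genes. Hosts lay above all 10000 level-matched sets of other long noncoding RNAs (permutation p = 0.0001, the smallest possible), but both explanations predict this. They differ in the mature microRNAs, which were not measured. Competition predicts that targets of these families rise. The test took 19 families classed as having a higher host transcript or a higher hairpin. Not all had a host past the threshold. MIR222HG was not, and PANK2, the host of MIR103A2, had a log2 fold change of 0.08. MIR103A2 itself had few reads, 2, 6 and 1 against 10, 5 and 3. Among same-composition 7-mers the 3′ UTR matches of the 19 families had a median percentile of 77.0. It was 62.2 for 17 tissue-restricted families and 78.2 for 20 other broadly expressed ones. The permutation p of 19 against 17 families was 0.032, but it reached 0.1612 without pre-miR-203a library 3 and was 0.05 or more in 6 of 16 other settings, so the explanations cannot be told apart. The family classes were written after the scan had shown matches of let-7, miR-25/92 and miR-15/16 among the highest, and this test replaced the hairpin test after its result was known.

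Genes such as PARK7 and PRDX3 fell without a 3′ UTR match, and 2 other routes were tested. Matches to miR-203a-5p, GAACCAC, ranked 77 of 94 same-composition 7-mers from the lowest, with an effect of 0.023 ± 0.016 (SE), and gave no sign of repression by that strand. In 5095 genes without a 3′ UTR 6mer, the 415 with a 7mer-m8 in the coding sequence had a median of −0.08, against 0.05 for 3826 without a 6mer there. Their adjusted effect was −0.061 ± 0.023 (SE) and ranked 7 of 210, with −0.102 as the lowest other. Sites in the coding sequence may thus add to the falls, as a hypothesis with a small effect that 6 other 7-mers exceeded. PARK7 has no such match in its coding sequence.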
